A study of Mus musculus with 10 samples.

How the data were processed

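The series measured messenger RNA by sequencing in small-intestinal epithelial cells of mice, 1 library per sample and 10 libraries in all. Per the labels, RNA was extracted with TRIzol and messenger RNA was selected with poly-T beads. The deposited values are FPKM, mapped fragments scaled to transcript length and to the fragments of the library, 1 column per library. The submitters' processing notes name HISAT2 and StringTie and the genome build GRCm38, and also tools for counts. Their versions, the role of each tool, the annotation, any filter on low values and the strand setting are not given in the sources used here. FPKM express each gene as a share of its library, so a few very abundant transcripts lower the values of all others. Where genes overlap or share sequence, the division of fragments between them is the submitters' and was not rechecked. This concerns the haemoglobin, defensin, serum amyloid and Sprr2a genes named in the report.

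The table held 24839 rows, of which 22036 carried an Ensembl identifier and 2803 were assembled transcripts without one. Of the Ensembl identifiers, 22022 were found in GENCODE release M21, which supplied the coordinates on GRCm38. Gene symbols are those of the submitters. In 27 rows the symbol had been turned into a date and was restored by its identifier. Every column of values per library was used. FPKM summed to between 539750 and 634280 per library. Neither counts nor read totals were used here, and they could not be recovered from the values. Low values lay within 0.1 of whole multiples of a step in 26.7% to 47.5% of cases, where chance gives 20%. The depth of each library is therefore unknown, and no counting interval is given.

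Libraries were grouped by their titles into NCD and HCD, 5 libraries each. HCD stands for the high cellulose diet of the series title, and the sources used here do not spell out NCD. The treatment label reads untreated for every NCD library and ovalbumin (OVA) for every HCD library, while the described design has both diets with and without OVA. The comparison of the titles can thus hold a difference in diet, in OVA or in both. It was not possible to separate them. Every NCD library has a lower library number than every HCD library, so a difference in handling could not be separated either.

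Genes with a mean of at least 1 FPKM over the 10 libraries were tested, 10321 in number. Values were taken as log2(FPKM + 1) without further scaling and fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend). Tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Differences are HCD minus NCD on the log2 scale, and fold differences are ratios of mean FPKM. The threshold of a fold of at least 2 was set on the log2(FPKM + 1) difference instead. Errors beside means are SD over 5 libraries. The p-values of limma, fry and the exact permutations measure the spread between these libraries. Those of camera and of permutation over genes set the genes of a list against other genes, and are not evidence from replicate libraries alone.

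A set of 36 gene lists was fixed before the data were examined, covering pathways, epithelial cell types, gut segments and other cells that an epithelial preparation can hold. Of these, 35 had at least 3 tested members. They were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01 and with adjustment over the 35 lists. The same test was run with a correlation estimated from the data. The fry test was run as well, which asks whether a list's genes move on balance in a single direction. An exact permutation test over libraries was added after the data had been seen: the mean of the list's members minus the mean of all tested genes was compared between the groups over all 252 splits, two-sided, with adjustment over the lists. Its smallest possible p is 0.00794 before adjustment, and a list can pass after adjustment only where several lists have p as low. For each list, the number of members that passed when adjusted over the list alone was also counted. The symbols Trac, Trdc, Trbc2, Ighm, Igha, Igkc and Prac1 had no row, and the antigen receptor genes behind most of them were thus not measured. G6pc1 and Bmal1 had no row either, but are further symbols of G6pc and Arntl, which were tested.

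Genes named in the report follow a rule fixed before the data were examined. They are the 12 largest rises and the 12 largest falls among genes that passed, had a gene name and reached 5 FPKM in at least 1 group. Added to them are up to 4 members of each list with the smallest p, and 11 genes for barrier and allergy that were named in advance: Muc2, Tjp1, Ocln, Cldn1, Cldn2, Il25, Il33, Tslp, Mcpt1, Reg3g and Pigr. Other genes are said to have been chosen after their values were seen.

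Separation of the groups was measured as the mean distance between groups minus the mean distance within groups, with 1 minus Pearson's r over the tested genes as the distance. It was tested by exact permutation over the 252 splits, one-sided. Shares of single libraries were compared by exact permutation, two-sided. Single libraries far from the other 4 of their group were sought with Dixon's ratio above 0.710.

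Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, other filters on low values, quantile normalization, median centring, rescaling to a common sum, eBayes without a trend or robust, library weights, a replicate block, the run of library numbers as a covariate, each run alone, a fold of at least 2 and leaving out each library. Added after the data had been seen were scaling without the 13 mitochondrially encoded genes, a correction for GC content and transcript length (available for 94.6% of tested genes other than the mitochondrial ones) and that scaling with HCD replicate 1, the library with the largest mitochondrial share, left out as well. A count-based alternative was not run because the values are FPKM. The main procedure was tested on simulated data with 200 changed genes among 10321. It recovered 24% of genes changed 1.5-fold, 45% of those changed 2-fold and 94% of those changed 4-fold, and called 6 unchanged genes. The simulated noise was independent between genes, rises and falls were equal in number, and no abundant transcripts shifted the scaling. These rates therefore need not hold for the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.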

Results

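Messenger RNA was sequenced from small-intestinal epithelial cells of 10 mouse samples, 5 with the title NCD and 5 with the title HCD, the high cellulose diet. In the described design the diets lasted 60 days. Mice were sensitised by injection on days 0 and 14 with 50 µg of ovalbumin (OVA, an egg white protein used to induce food allergy) and 1 mg of alum. They then received 5 oral doses of 50 mg of OVA, with saline in unsensitised groups. The treatment label puts OVA with every HCD library and no treatment with every NCD library. Each difference given here can thus come from diet, from OVA or from both. Library numbers follow the groups too, between 1 and 10 in NCD and between 11 and 20 in HCD. A difference in handling that goes with these numbers cannot be told apart either. Values are FPKM, scaled by the submitters, and the depth of each library is unknown. Between 13577 and 16240 genes and assembled transcripts were above 0 in each library, and 9844 to 10455 genes reached 1 FPKM.

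The libraries differed in 3 shares of their summed FPKM. The 13 genes encoded in the mitochondrial genome took 4.53% ± 1.11 (SD, n = 5) in NCD and 19.4% ± 5.89 in HCD, 4.27 times as much, and all HCD libraries lay above all NCD libraries (exact permutation p = 0.00794, adjusted p = 0.0159 over 6 library measures, two-sided). Haemoglobin transcripts took 0.00460% ± 0.00183 in NCD and 0.0404% ± 0.0186 in HCD, 8.79 times as much (exact permutation p = 0.00794, adjusted p = 0.0159). The 10 highest genes of each library, mitochondrial ones among them, took 10.6% ± 1.14 in NCD and 23.95% ± 4.01 in HCD (exact permutation p = 0.00794, adjusted p = 0.0159). Library numbers fell into a run of replicates 1 to 3 and a run of replicates 4 and 5 in each group, and no label says what the numbers mean. The mean mitochondrial share was 3.85% in NCD and 21.2% in HCD among replicates 1 to 3, and 5.56% and 16.6% among replicates 4 and 5. For haemoglobin it was 0.00439% and 0.0528% among replicates 1 to 3, and 0.00492% and 0.0218% among replicates 4 and 5.

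**Figure D1:**
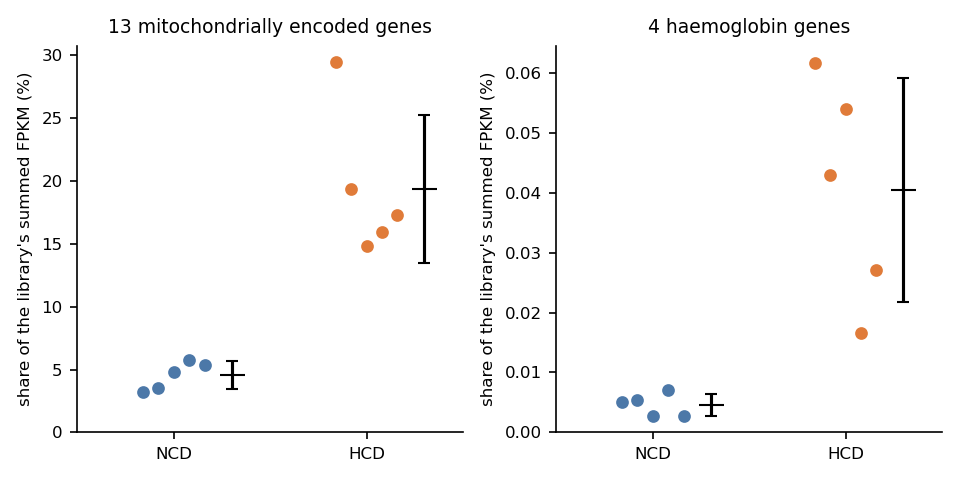
Share of the summed FPKM of each library, in percent, taken by the 13 mitochondrially encoded genes (left) and by 4 haemoglobin genes (right) in NCD and HCD; points are libraries, and bars give the mean and SD over 5 libraries. The mitochondrial share ran from 3.23% to 5.76% in NCD and from 14.8% to 29.5% in HCD.

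The comparison of HCD with NCD asks how the epithelial preparations of mice with these titles differed in their transcripts. T cell genes and mitochondrially encoded genes were higher in HCD. Of genes of cell junctions 12 of 20 were lower, as were 13 of 21 of the response to stress in the endoplasmic reticulum, where 1 was higher. Camera called these lists and the T cell list at a preset correlation between genes, and none of the 3 with an estimated one. Among named genes that reached 5 FPKM in a group, Ada, which breaks down adenosine, had the largest rise in log2(FPKM + 1). Ada went from 11.9 ± 10.5 to 234 ± 97.1 FPKM (SD, n = 5), 19.7-fold. With a pseudocount of 0.1 the log2 differences of Clca4a (5.42) and Saa1 (5.36) exceeded that of Ada (4.53). As ratios of mean FPKM, rises such as those of Saa1, Clca4a and Slc28a2 were larger than that of Ada. F3, tissue factor, which starts coagulation, had the largest fall, from 47.2 ± 11.7 to 7.88 ± 6.14 FPKM, 5.99-fold lower. Of 10321 tested genes, 2718 passed at an adjusted p under 0.05 in limma, 736 higher and 1982 lower in HCD. A fold of at least 2 on the log2(FPKM + 1) scale was met as well by 383 of the higher and 222 of the lower genes. With the mitochondrial genes left out of the scaling the numbers were 459 and 95.

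The median difference over all tested genes was -0.19 on the log2 scale. When the 13 mitochondrial genes were left out of the scaling, a setting added after the data had been seen, it was -0.05, and 1784 genes passed, 923 higher and 861 lower. All of these 861 lower genes and 722 of the 923 higher ones had passed in the same direction as deposited. Of the genes that passed, 27.1% were higher as deposited and 51.7% in that setting. Medians of the gene groups that camera called down are therefore given on both scales. No gene that passed on both scales changed direction. The groups separated by 0.0265 in distance, 1 minus Pearson's r (exact permutation p = 0.00794, one-sided). Pearson's r between libraries was 0.959 to 0.980 within NCD, 0.950 to 0.975 within HCD and 0.909 to 0.961 between the groups. Within the runs of library numbers, 1420 genes passed among replicates 1 to 3 (3 libraries per group) and 56 among replicates 4 and 5 (2 per group).

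**Figure D2:**
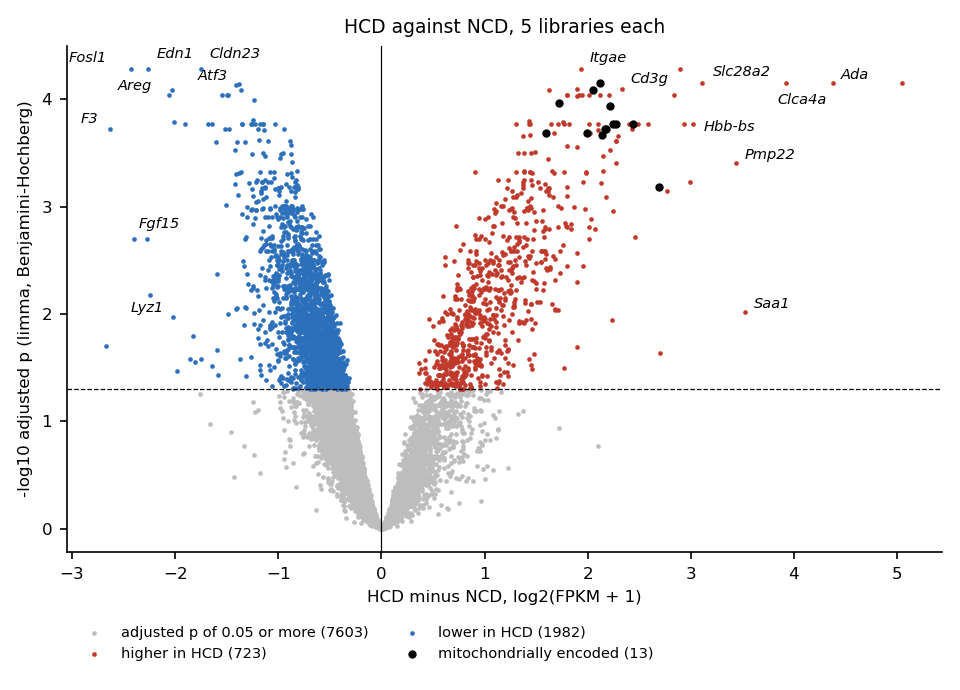
Log2 difference HCD minus NCD (x axis) against minus log10 of the limma adjusted p (y axis) for 10321 genes; points are genes, with higher genes, the 13 mitochondrial genes and lower genes in their own colours. Of the genes that passed, 736 lie to the right and 1982 to the left, and all 13 mitochondrial genes lie to the right.

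T cell genes rose together in HCD. Of 16 measured members of the T cell and intraepithelial lymphocyte list, 15 rose, also 15 when adjusted over the list alone, and Cd2 was the exception (log2 difference 0.51). Cd7 went from 56.3 ± 29.3 to 332 ± 131 FPKM, 5.91-fold. Ccl5, a chemokine of cytotoxic lymphocytes, went from 213 ± 109 to 1104 ± 301 FPKM, 5.19-fold. Cd3g, a chain of the T cell receptor complex on chromosome 9 (44969572 to 44980431), went from 17.4 ± 4.66 to 94.3 ± 34.6 FPKM (log2 difference 2.34 ± 0.24 SE, adjusted p = 8.15e-05). Itgae, the integrin CD103 that holds lymphocytes in the epithelium, on chromosome 11 (73090583 to 73147446), went from 5.86 ± 1.40 to 25.0 ± 2.41 FPKM (log2 difference 1.94 ± 0.16 SE, adjusted p = 5.2e-05). In all 4 genes each HCD library was above each NCD library, as in 468 of all 10321 tested genes on the deposited scale. Over the list the median was 2.05 on the log2 scale, or 2.20 with the mitochondrial genes left out of the scaling. Camera gave an adjusted p of 4.8e-21 at the preset correlation and adjusted p = 0.194 with an estimated correlation, while the exact permutation of library means gave an adjusted p of 0.0463. The list's median lay above that of all genes by 2.95 in replicates 1 to 3 and by 1.49 in replicates 4 and 5.

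All 4 measured haemoglobin genes rose, by log2 differences of 2.83 to 3.02. Hbb-bs, a chain of adult haemoglobin, went from 12.97 ± 7.03 to 112 ± 49.5 FPKM. The red blood cell list, which these 4 genes made up, passed in camera (adjusted p = 1.9e-07) and in the permutation of library means (exact, adjusted p = 0.0463), with adjusted p = 0.194 with an estimated correlation. Hba-a1 and Hba-a2 are near copies in sequence, as are Hbb-bs and Hbb-bt, so reads can be shared within each pair and the 4 genes are not independent. Among markers of other cells, 2 of 3 tested stromal and endothelial genes, of 16 listed, rose: Vim went from 6.35 ± 1.34 to 14.8 ± 3.18 FPKM and Pecam1 from 2.06 ± 0.271 to 4.22 ± 1.37 FPKM, both genes that leukocytes make too, while Tagln, of smooth muscle, differed by 0.16 (adjusted p = 0.609). This list's adjusted p was 0.00763 in camera, adjusted p = 0.194 with an estimated correlation and 0.0463 by permutation of library means. Without a filter on low values camera did not call it (adjusted p = 0.0623), and its median above that of all genes was 0.04 in place of 0.93. Of 13 myeloid genes 3 rose, Itgax (1.14), Fcer1g (1.45) and Tyrobp (1.48, adjusted p = 0.0235), which intraepithelial lymphocytes can also make. Tyrobp no longer passed without NCD replicate 3 (adjusted p = 0.0534), HCD replicate 1 (0.0561) or HCD replicate 3 (0.0548). Cd68, a macrophage gene, differed by 0.66 (adjusted p = 0.140), and by 0.92 without NCD replicate 4 (adjusted p = 0.0228). Of 8 B cell genes 1 rose, Jchain, the joining chain of secreted antibodies, from 20.6 ± 5.48 to 46.7 ± 8.61 FPKM. Mzb1 (1.04), Cd22 (0.49) and Cd79a (0.72) did not pass, but did without NCD replicate 2, at 1.42, 0.79 and 1.27. Mzb1 also passed with the mitochondrial genes left out of the scaling (1.19, adjusted p = 0.0442). The B cell list's median above that of all genes was 0.71, or 1.21 without NCD replicate 2 and 0.43 without NCD replicate 3. Camera called the myeloid list (median 0.47, adjusted p = 1.1e-04) and the B cell list (median 0.52, adjusted p = 0.00498). With an estimated correlation the adjusted p was 0.410 and 0.530, and by permutation of library means (exact) 0.123 and 0.227. None of 7 mast cell genes passed in limma, and their list was not called (median 0.15, adjusted p = 0.127). Mcpt1, a mucosal mast cell protease, was at 251 ± 172 in NCD and 237 ± 68.3 FPKM in HCD (adjusted p = 0.869).

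All 13 mitochondrially encoded genes rose, by 1.60 (mt-Nd6) to 2.69 (mt-Nd3) on the log2 scale, and 12 of them still rose after quantile normalization. mt-Nd3 went from 136 ± 45.8 to 1120 ± 1130 FPKM, with HCD replicate 1 at 3138 FPKM. Among the nuclear genes of the same respiratory chain, 13 of 26 in the oxidative phosphorylation list fell, 18 when adjusted over the list alone, and none rose. Uqcrc2 fell by 0.78, Cox5a by 0.70, Atp5a1 by 0.67 and Ndufs3 by 0.61 on the log2 scale. After quantile normalization Uqcrc2 differed by -0.49 (adjusted p = 0.0572). With the mitochondrial genes left out of the scaling, 7 of the 26 passed as lower, against 5 after quantile normalization, and the median moved from -0.45 to -0.28. Camera's adjusted p was 1.9e-04, with adjusted p = 0.530 with an estimated correlation and 0.0833 by permutation of library means (exact). Of 21 genes of fatty acid oxidation and ketogenesis 8 fell, 11 when adjusted over the list alone, 5 with the mitochondrial genes left out of the scaling and 4 after quantile normalization. Cpt1a, which brings fatty acids into mitochondria, fell from 49.6 ± 12.4 to 26.3 ± 2.61 FPKM. Pdk4, which slows the use of sugar carbon, fell from 75.5 ± 14.1 to 36.6 ± 12.2 FPKM. Hadhb (-0.88) and Acadvl (-0.54), which break down fatty acids, fell too. Acadvl did not pass after quantile normalization (-0.26, adjusted p = 0.109), nor with HCD replicate 1 and the mitochondrial genes both left out (-0.36, adjusted p = 0.0609). The list's median was -0.45, or -0.28 with the mitochondrial genes left out of the scaling. Camera's adjusted p was 0.00372, with adjusted p = 0.531 with an estimated correlation and 0.0617 by permutation of library means (exact).

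Most measured genes of tight and adherens junctions fell. Of 20 measured members 12 fell, 13 when adjusted over the list alone, and none rose. Cldn23, a claudin of the tight junction on chromosome 8 (35824712 to 35826559), fell from 243 ± 31.5 to 72.4 ± 17.0 FPKM, 3.36-fold lower (log2 difference -1.75 ± 0.15 SE, adjusted p = 5.2e-05). Cldn4, on chromosome 5 (134945119 to 134946934), fell from 465 ± 102 to 155 ± 51.3 FPKM. Cldn3, on chromosome 5 and the most abundant of these 3 claudins, fell from 1966 ± 206 to 1038 ± 171 FPKM. Marveld2, tricellulin, which seals the corners between 3 cells, fell from 17.4 ± 2.76 to 6.91 ± 1.98 FPKM. Ocln, occludin, fell from 21.4 ± 6.71 to 9.05 ± 3.47 FPKM (adjusted p = 0.00432), and Cldn2, which forms a channel for ions, from 15.96 ± 6.39 to 6.31 ± 1.33 FPKM (adjusted p = 0.00374). In all 6 genes each HCD library was below each NCD library, as in 1327 of all 10321 tested genes on the deposited scale. Tjp1, the scaffold protein ZO-1, was at 3.52 ± 0.568 and 2.40 ± 0.868 FPKM and did not pass (adjusted p = 0.126). The median over the junction list was -0.64, or -0.47 with the mitochondrial genes left out of the scaling, where 10 members passed as lower, and 9 did after quantile normalization. It passed in camera (adjusted p = 3.6e-05) and by permutation of library means (exact, adjusted p = 0.0463), with adjusted p = 0.410 with an estimated correlation.

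Other genes chosen in advance for barrier and allergy differed by less than the test could separate from the spread of the libraries. Muc2, the main gel-forming mucin, was at 444 ± 34.4 FPKM in NCD and 411 ± 234 in HCD (adjusted p = 0.487). HCD replicate 5 stood at 828 FPKM and the other HCD libraries at 297 to 316, and without it Muc2 was lower by a log2 difference of -0.53 (adjusted p = 0.00755). Il33, an epithelial alarmin, differed by 0.13 (adjusted p = 0.716), Pigr, which carries antibodies across the epithelium, by 0.14 (adjusted p = 0.823) and Reg3g, an antimicrobial lectin, by -0.31 (adjusted p = 0.617). Il25, an alarmin of tuft cells, had a mean of 0.0185 FPKM in NCD and 0.0934 in HCD, and Cldn1 of 0.0287 and 0.114, all under the minimum for testing. Tslp was listed at 0 in every library. None of the 6 tested genes of the alarmin and type 2 cytokine list passed in limma (median 0.11, camera adjusted p = 0.162).

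Most measured genes that respond to stress in the endoplasmic reticulum fell. Of 21 measured members 13 fell, 16 when adjusted over the list alone. Atf3, a stress-induced transcription factor on chromosome 1 (191170296 to 191218039), fell from 1001 ± 105 to 386 ± 54.9 FPKM (log2 difference -1.38 ± 0.14 SE, adjusted p = 7.2e-05). Hyou1, Manf and Pdia6, which help proteins fold, fell by 1.19, 1.27 and 1.13 on the log2 scale, with every HCD library below every NCD library. Trib3, a pseudokinase induced by stress and chosen after its values were seen, was the 1 member that rose (0.75). The median over the list was -0.70, or -0.53 with the mitochondrial genes left out of the scaling, where 11 members passed as lower, and 10 did after quantile normalization. It passed in camera (adjusted p = 8.4e-05) and by permutation of library means (exact, adjusted p = 0.0463), with adjusted p = 0.410 with an estimated correlation.

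Part of the enterocyte markers were higher in HCD. Of 11 members 5 rose, also 5 when adjusted over the list alone: Ada, Apoa1, Apoa4, Krt20 and, chosen after its values were seen, Fabp2 (0.68). Apoa1, an apolipoprotein packed with absorbed fat, was at 9978 ± 3312 FPKM in NCD and 19183 ± 4290 in HCD (adjusted p = 0.0162), a difference that changed sign to -0.24 after quantile normalization and missed the threshold without NCD replicate 1 (adjusted p = 0.0525). Apoa4 was at 4614 ± 927 and 7954 ± 1619 FPKM (adjusted p = 0.0118). After quantile normalization its difference was 0.09 (adjusted p = 0.802). Krt20, a keratin of the villus, was at 296 ± 73.6 and 447 ± 105 FPKM (adjusted p = 0.0405) and failed the threshold without NCD replicate 1, 2 or 4 or HCD replicate 2, 3, 4 or 5, with an adjusted p of up to 0.109. With quantile normalization 2 of the 11 passed as higher, after rescaling to TPM 3 and with the mitochondrial genes left out of the scaling 6. The median of the 11 was 0.35, or 0.53 in the last of these. It passed in camera (adjusted p = 7.9e-05) and by permutation of library means (exact, adjusted p = 0.0463), with adjusted p = 0.394 with an estimated correlation. Without Ada the mean of the other 10 members, measured against all tested genes, was still higher in HCD by 0.52 (exact permutation p = 0.0159, unadjusted).

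Parts of the lists for dividing cells and for Paneth cells, which sit in the crypts, were lower in HCD. Of 21 proliferation genes 11 fell, 15 when adjusted over the list alone, or 4 with the mitochondrial genes left out of the scaling and 6 after quantile normalization. Ccnb2, a cyclin of mitosis, fell from 17.1 ± 10.2 to 5.51 ± 1.23 FPKM, Ube2c from 48.1 ± 27.6 to 16.2 ± 6.74, Ccnb1 from 7.09 ± 5.06 to 1.62 ± 0.323 and Tk1 from 27.1 ± 8.43 to 14.2 ± 3.16. The median was -0.82, or -0.67 with the mitochondrial genes left out of the scaling. Camera's adjusted p was 0.00649, with adjusted p = 0.631 with an estimated correlation and 0.123 by permutation of library means (exact). Against all genes the median lay at -0.84 in replicates 1 to 3 and at -0.05 in replicates 4 and 5, where camera did not call it (adjusted p = 0.573). Of 11 Paneth cell genes 6 fell, 7 when adjusted over the list alone, or 4 with the mitochondrial genes left out of the scaling and 3 after quantile normalization. Lyz1, the lysozyme of Paneth cells, fell from 184 ± 108 to 47.3 ± 34.5 FPKM (adjusted p = 0.0106). The defensins Defa17 (-1.82, adjusted p = 0.0161) and Defa30 (-1.81, adjusted p = 0.0279) fell, as did Mptx2 (-1.33) and Ang4 (-1.20). Defa35, outside the list, fell by 1.98 on the log2 scale (adjusted p = 0.0340). With the mitochondrial genes left out of the scaling, Defa30 (adjusted p = 0.0591) and Defa35 (adjusted p = 0.0692) no longer passed. Nor did Defa17 (0.0531), Defa30 (0.0778) and Defa35 (0.0692) after quantile normalization. Leaving out NCD replicate 1 (adjusted p = 0.0763 and 0.0859), NCD replicate 3 (0.0680 and 0.0815), HCD replicate 2 (0.0614 and 0.0685) or HCD replicate 3 (0.0686 and 0.0523) ended both calls, and leaving out NCD replicate 5 ended that of Defa35 (0.0596). The Paneth cell list's median was -1.33, or -1.19 with the mitochondrial genes left out of the scaling. Camera's adjusted p was 0.0185, and 0.0790 without HCD replicate 2 or 0.0513 without HCD replicate 3. It was called neither with an estimated correlation (adjusted p = 0.603) nor by permutation of library means (exact, adjusted p = 0.139).

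Among rarer epithelial cells, 3 of 13 enteroendocrine genes rose, 6 when adjusted over the list alone, also 6 with the mitochondrial genes left out of the scaling and 5 after quantile normalization. Nts, the gut peptide neurotensin, went from 1.32 ± 0.838 to 7.89 ± 2.48 FPKM, Sct, secretin, from 61.1 ± 27.9 to 208 ± 110 and Tph1, which makes serotonin, from 10.1 ± 0.724 to 19.4 ± 4.78. Pyy differed by 0.89 (adjusted p = 0.0569), and passed without NCD replicate 5 (1.13) or HCD replicate 4 (1.11) and with the mitochondrial genes left out of the scaling (1.04). The list's median was 0.71, or 0.88 with the mitochondrial genes left out of the scaling (camera adjusted p = 1.9e-04, with adjusted p = 0.410 with an estimated correlation and 0.0617 by exact permutation of library means). In replicates 4 and 5 camera did not call it (adjusted p = 0.232). Of 8 tuft cell genes 1 rose, none when adjusted over the list alone: Alox5, of leukotriene synthesis (0.73, adjusted p = 0.0438). Alox5 failed the threshold without NCD replicate 1, 3 or 5 or HCD replicate 1, 3, 4 or 5, with an adjusted p of up to 0.112. It also failed with the replicate block (0.0783) or the run of library numbers as a covariate (0.0528). Quantile normalization (0.0662) and rescaling to TPM (0.0523) ended the call as well. Siglecf (0.77, adjusted p = 0.0643) passed without NCD replicate 5 (0.94) or HCD replicate 2 (0.93), Alox5ap (0.67, adjusted p = 0.153) without HCD replicate 2 (0.96) and Sh2d6 (0.79, adjusted p = 0.155) without HCD replicate 5 (1.18). The tuft cell list's median was 0.55 (camera adjusted p = 0.0187, with adjusted p = 0.410 with an estimated correlation and 0.123 by exact permutation of library means). It was not called without NCD replicate 3 (adjusted p = 0.0712), HCD replicate 1 (0.0590) or HCD replicate 3 (0.0523), after quantile normalization (0.0814) or in replicates 4 and 5 (0.232). None of 12 goblet cell genes passed in limma, also when adjusted over the list alone.

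Lists of immune signalling had higher medians in HCD, with few single members past the test. Of 15 interferon-response genes 5 rose, or 7 with the mitochondrial genes left out of the scaling. Zbp1, a sensor of nucleic acids, went from 6.73 ± 0.992 to 15.7 ± 5.02 FPKM and Irf7 from 74.9 ± 8.68 to 115 ± 11.7 FPKM. Usp18 (0.69) and Isg15 (0.84, adjusted p = 0.0329) rose too. Isg15 missed the threshold without NCD replicate 1, 2 or 3 or HCD replicate 1, 3 or 4, with an adjusted p of up to 0.0778. The median was 0.25, or 0.41 with the mitochondrial genes left out of the scaling (camera adjusted p = 1.5e-04, with adjusted p = 0.410 with an estimated correlation and 0.0617 by exact permutation of library means). Of 13 genes of NF-kB signalling and acute inflammation 1 rose and 1 fell. Tnfaip3, an inhibitor of this pathway, went from 20.7 ± 4.42 to 46.2 ± 7.86 FPKM, and Nfkbia, another of its inhibitors, fell from 111 ± 12.4 to 70.4 ± 9.33. Icam1 (0.72, adjusted p = 0.0938) passed without NCD replicate 2 (0.90) and Tnfaip2 (0.65, adjusted p = 0.114) without HCD replicate 2 (0.90). The median was 0.44 (camera adjusted p = 0.00872, with adjusted p = 0.410 with an estimated correlation and 0.119 by exact permutation of library means). None of 10 genes of antigen presentation on MHC class II passed in limma, though camera called the list (median 0.47, adjusted p = 0.0119, with adjusted p = 0.566 with an estimated correlation and 0.229 by exact permutation of library means). Without NCD replicate 1 the list was not called (adjusted p = 0.0841), and its median above that of all genes moved from 0.67 to 0.42. H2-Ab1 (0.73), H2-Aa (0.46), H2-Eb1 (0.59) and Cd74 (0.52) had adjusted p of 0.0688 to 0.174. H2-Ab1 passed with the mitochondrial genes left out of the scaling (adjusted p = 0.0421) and without NCD replicate 2 (0.0224) or NCD replicate 5 (0.0473), and H2-Aa (0.0381) and H2-Eb1 (0.0393) without NCD replicate 2.

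**Figure D3:**
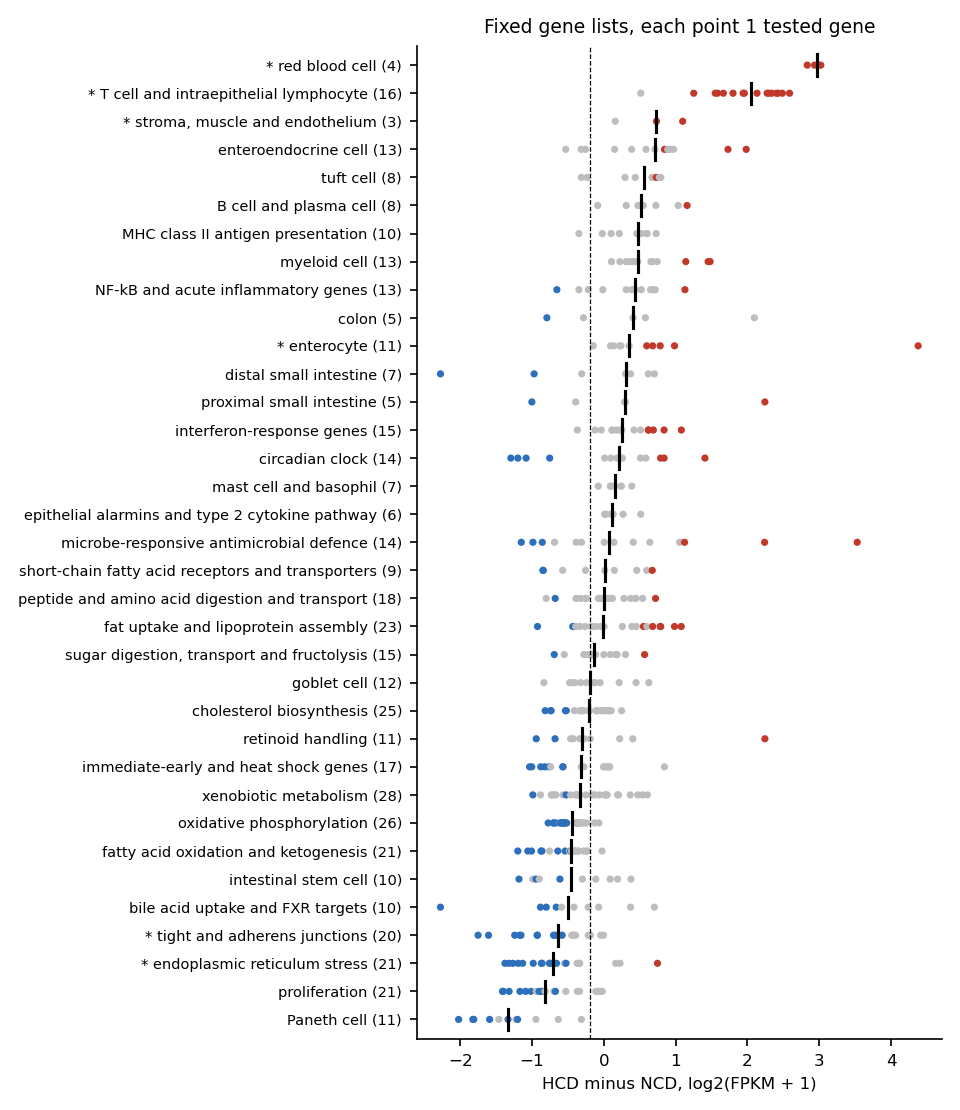
Log2 difference HCD minus NCD (x axis) of the tested members of 35 gene lists (one line each, tested members in brackets); points are genes, in red where higher, blue where lower and grey where not passed, black bars are medians, the dashed line is the median of all tested genes (-0.19) and stars mark lists called by exact permutation of library means. The T cell list has its median at 2.05, the junction list at -0.64 and the endoplasmic reticulum stress list at -0.70, and Apoa1 in the enterocyte list changes sign after quantile normalization.

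Of the remaining largest rises, Clca4a, a gene of the calcium-activated chloride channel regulator family on chromosome 3 (144952480 to 144975045), went from 0.613 ± 0.810 to 25.4 ± 17.1 FPKM. Slc28a2, which takes up purine nucleosides, went from 0.782 ± 0.288 to 15.8 ± 8.03 FPKM (log2 difference 3.11 ± 0.29 SE). Ada, on chromosome 2 (163726584 to 163750239), acts on the same nucleosides, with a log2 difference of 4.38 ± 0.43 SE (adjusted p = 7.0e-05). Pmp22, a membrane protein best known from myelin, went from 6.87 ± 6.12 to 89.9 ± 73.5 FPKM. Saa1, serum amyloid A, had a log2 difference of 3.53 (adjusted p = 0.00954) and ran from 0.708 to 164 FPKM in HCD. The size of such differences depends on the pseudocount where NCD values are low. With pseudocounts of 0.1 and 5 they were 5.36 and 2.14 for Saa1 and 4.08 and 1.76 for Slc28a2, and both genes still passed. The Saa1 difference was 2.70 without HCD replicate 1 and 4.35 without HCD replicate 2. Sprr2a2, a small proline-rich protein (2.71, adjusted p = 0.0229), missed the threshold without HCD replicate 3 (2.41, adjusted p = 0.0558). The same held with a pseudocount of 5 (1.54, adjusted p = 0.0583) and with robust eBayes (0.0689). It held too without a filter on low values (0.0883) and after quantile normalization (0.0501). Sprr2a2 differed by 1.87 without HCD replicate 1 and by 3.31 without HCD replicate 2. Of the remaining largest falls, Fosl1, a subunit of the AP-1 transcription factor on chromosome 19 (5447547 to 5455946), went from 44.5 ± 9.75 to 7.71 ± 3.17 FPKM (log2 difference -2.42 ± 0.22 SE). Areg, amphiregulin, a ligand of the EGF receptor on chromosome 5 (91139599 to 91148432), fell from 349 ± 67.5 to 87.9 ± 31.5 FPKM. The endothelins Edn1 and Edn2, vessel-constricting peptides, fell from 47.5 ± 10.5 to 9.15 ± 2.86 and from 114 ± 29.1 to 30.8 ± 12.3 FPKM. Phlda1 fell from 83.0 ± 22.4 to 20.3 ± 7.44 and Phlda2 from 13.6 ± 5.61 to 2.38 ± 0.541 FPKM. Fgf15, the intestinal hormone that curbs bile acid synthesis in the liver, fell from 36.3 ± 16.3 to 7.87 ± 7.50 FPKM (adjusted p = 0.0020). F3 lies on chromosome 3 (121723537 to 121735048), with a log2 difference of -2.63 ± 0.33 SE. Except for Fgf15, each HCD library was below each NCD library in these lower genes.

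**Figure D4:**
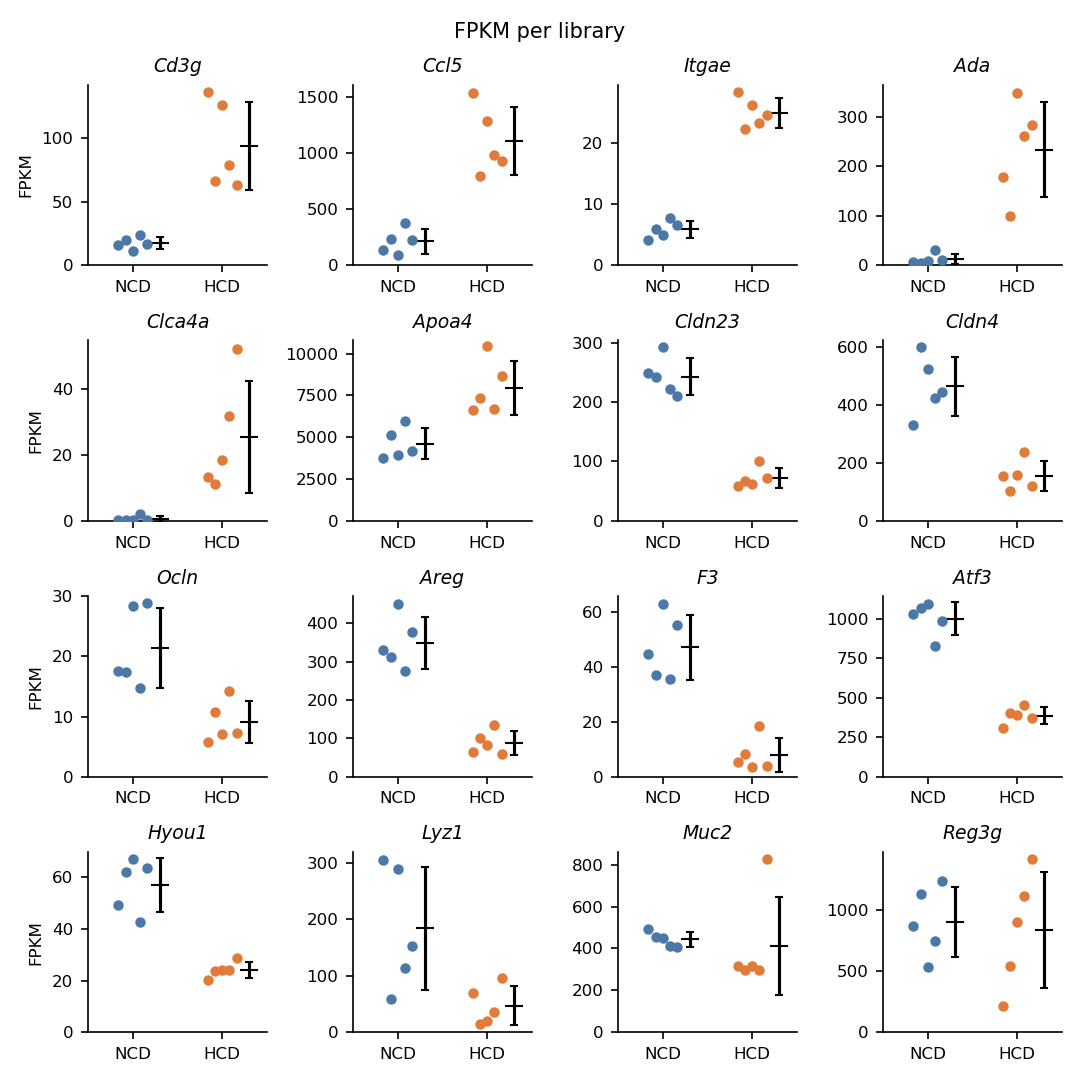
FPKM of 16 genes in each NCD and HCD library; points are libraries, and bars give the mean and SD over 5 libraries. Cd3g, Ccl5, Itgae and Ada lie higher and Cldn23, Cldn4, Ocln, Areg, F3, Atf3 and Hyou1 lower in every HCD library than in any NCD library, while HCD libraries lie both above and below the NCD range in Muc2 and Reg3g.

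In all, camera called 17 of 35 lists at the preset correlation, 11 up and 6 down. None was called with an estimated correlation, where 4 had an unadjusted p under 0.05. The fry test called 10 lists, 4 up and 6 down, 8 of them among the 17. The others were the bile acid list (adjusted p = 0.00938) and the immediate-early list (adjusted p = 0.0162), both down. The fry test was run only as deposited, where the median difference over all tested genes was -0.19. It does not set a list against other genes, so its down calls can hold part of that shift. Permutation of library means called 6, all among the 17. T cell, red blood cell, enterocyte and stromal genes were up, and junction and endoplasmic reticulum stress genes down. All 6 had the smallest possible exact permutation p of 0.00794 and thus the same adjusted p of 0.0463. With fewer lists at that p none would have passed, so these calls depend on each other. Lists that camera did not call were those of sugar handling, peptide handling, cholesterol synthesis, bile acids, xenobiotics, retinoids, short-chain fatty acids, fat uptake, the clock, immediate-early genes, antimicrobial defence, alarmins, stem cells, goblet cells, mast cells and the 3 gut segments. Their adjusted p ran from 0.0530 for fat uptake and lipoprotein assembly to 0.872 for xenobiotic metabolism. With the mitochondrial genes left out of the scaling, camera also called the fat uptake list, as up (adjusted p = 0.0175, and 0.474 with an estimated correlation). The pancreatic list had 1 tested member, Cela1 (0.83), named after its values were seen.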

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

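The tests of mitochondrial DNA, of a joint rise of respiratory chain genes, of damaged cells, of a lower share of epithelium, of fewer crypts and of scaling were chosen after the results were seen. The tests of blood, of intraepithelial lymphocytes and of the villus tip were chosen after the patterns they address were seen. Their genes were fixed before these were looked at as a set, though some blood and villus tip genes stand in lists tested earlier. The test of other splits of the libraries was chosen before its outcome was seen.

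Single libraries stood far from the other 4 of their group in 12 of 226 sets of 5 values, where chance gives about 11.3, so their number alone is no sign of a problem. Clca4a was at 2.06 FPKM in NCD replicate 4, against 0.208 to 0.289 in the other NCD libraries. Pmp22 was at 17.8 FPKM in the same library, against 3.53 to 4.82. Edn1 was low there, at 29.9 FPKM against 49.2 to 58.1. mt-Nd3 reached 3138 FPKM in HCD replicate 1, against 489.8 to 682 in the other HCD libraries. Cd68 was at 9.47 FPKM in that library, against 3.08 to 4.04. Tnfaip2 was at 4.50 FPKM in HCD replicate 2, against 10.9 to 14.1. In HCD replicate 4, Zbp1 stood at 24.5 FPKM against 11.9 to 14.2, and H2-Aa at 259 against 201 to 211. Tk1 was at 8.95 FPKM in HCD replicate 3, against 14.5 to 17.5. In HCD replicate 5, Sh2d6 was at 1.32 FPKM against 7.13 to 9.12, and Muc2 at 828 against 297 to 316. Tjp1 was at 4.50 FPKM in NCD replicate 3, against 3.09 to 3.46.

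T cell genes were higher in HCD by a median of 2.20 on the log2 scale with the mitochondrial genes left out of the scaling. Blood as the source of these is argued against by 7 tested genes of circulating leukocytes, from a list of 10 of which 6 also stand in the B cell or myeloid lists: their median was 0.70 (permutation p = 7.0e-05 over genes, exact p = 0.0159 over libraries), though red blood cells themselves are not excluded, since 4 haemoglobin genes had a median of 3.12. A lower share of epithelium would raise all other cells alike. However, 31 markers of B, mast, myeloid and stromal cells had a median of 0.58, below that of T cells (exact permutation p = 0.00794 over libraries). On the log2(FPKM + 1) scale differences shrink where FPKM are low. Part of the gap between T cell genes and either set can come from this where the compared genes have lower FPKM. The effect of the pseudocount on these gaps was not tested. More intraepithelial lymphocytes in the HCD preparations may be a candidate explanation, as 5 further genes of these cells, Itgb7 (1.96), Klrd1 (2.25), Cd160 (2.23), Cd244a (0.92) and Ccr9 (0.82), had a median of 1.96. Whether this comes from the mice, from diet or OVA, or from how the cells were prepared is open, and no sort or gate is named that would remove lymphocytes.

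Mitochondrially encoded transcripts were higher in HCD by a median of 2.17 on the log2 scale, while the share they took of each library rose from 4.53% to 19.4%. DNA carried into the libraries would add similar amounts to all 13 genes, but the largest gain was 12.7 times the median gain and the smallest 0.164 times. This argues against DNA as the only source. A smaller even part from DNA is not excluded, since the smallest gain was 513 FPKM (mt-Nd4l). A joint rise of the respiratory chain is argued against by its 26 nuclear genes, with a median of -0.28 (bootstrap SE 0.0787) with the mitochondrial genes left out of the scaling. Damaged cells or lower RNA quality cannot be told apart from a biological difference, since 0 nuclear-retained RNAs were among the transcripts and any damage would follow the groups. A difference that comes with diet or OVA stays open and was not tested.

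Paneth cell and proliferation genes were lower in HCD by a mean of -0.93 (SE 0.36) as deposited over 32 genes. Scaling to a total that mitochondrial transcripts share cannot be told apart as a contributor: without those transcripts the mean was -0.79 (SE 0.37), so that the exact permutation p moved from 0.0397 to 0.0794 with the mean nearer 0 at a similar SE. Of 17 genes called, 8 kept their call, the median of the 17 was -1.20 before and -1.09 after (median SE 0.34 after), and the adjustment over all genes changed as well. Fewer crypts would lower stem cell genes alike, and their median lay above that of Paneth cells by 0.84 (permutation p = 0.00252 over genes, 0.0281 without Cd44, Myc and Prom1), but exact p = 0.0794 over libraries, or 0.206 without these 3, leaves this open. A shift towards the villus tip was left open too, with a median of 0.33 (SE 0.298) over 6 further genes of the tip, of which Apob and Mttp also stand in the fat uptake list, and no test separated these explanations.

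Of 100 drawn splits of the 10 libraries into 5 and 5, out of 126 possible, 1 gave as many genes as the real one, the real split itself. It gave 2718 genes against at most 5 in any other, or 1784 against at most 23 with the mitochondrial genes left out of the scaling. The other splits mix the groups, so the group difference adds to their spread and lowers their counts. The size of the gap is thus partly built in. A rank of 1 among 100 argues against chance for the number of genes without excluding it. It does not bear on a technical difference that follows the groups. For gene lists by camera at the preset correlation, 18 of the 100 splits gave as many as the real 17, and the highest other gave 22. Chance is thus not excluded for the number of lists called that way.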

How the results depend on the processing

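The settings without mitochondrial genes in the scaling, the correction for GC content and length and the exact permutation of list means were chosen after the data had been seen. The number of genes that passed (2718) was 1811 after quantile normalization, 1784 when scaled without mitochondrial genes, 1618 with HCD replicate 1 left out as well, 1420 in replicates 1 to 3 only, 56 in replicates 4 and 5 only and 605 with a fold of at least 2. Higher genes (736) were 414 and 45 in these runs and 383 with the fold. Lower genes (1982) were 883 after quantile normalization, 1053 after median centring, 861 without mitochondrial genes, 783 with HCD replicate 1 left out as well, 1006 and 11 in the runs and 222 with the fold. Leaving out each library gave 1889 to 2778 genes, 551 to 787 higher and 1319 (without NCD replicate 1) to 2036 lower. The runs hold fewer libraries, and the cause of the other differences was not tested. No gene passed in opposite directions in any of these settings. Lists called (17) were 0 with an estimated correlation, 10 with fry, 6 by exact permutation of library means and 15 to 18 when a library was left out. Of 89 named genes that passed, 14 kept direction and call in every setting, 75 lost the call in at least 1, mostly in replicates 4 and 5 only, and 1 changed sign: Apoa1, -0.24 after quantile normalization (adjusted p = 0.427). Sign changes among genes that had not passed were Sh2d6 (-0.37), Muc2 (0.28) and Reg3g (0.38) in replicates 4 and 5, Tagln (-0.16) and Mcpt1 (-0.29) in replicates 1 to 3, Muc2 (0.052) after quantile normalization and Reg3g (0.27) with HCD replicate 1 left out and scaled without mitochondrial genes. When each library was left out, Mcpt1 ran from -0.13 to 0.43, Il33 from -0.023 to 0.28, Pigr from -0.17 to 0.34 and Reg3g from -0.57 to 0.12. The causes were not tested. A count-based alternative was not run because the values are FPKM, camera has no robust form, and the unknown depth leaves counting error out of every value.

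With a replicate block, the separation was 0.0265 (p = 0.0625 by exact permutation, the smallest that 32 swaps can give), 2293 genes passed (673 higher, 1620 lower) and 17 lists were called. No label says whether replicate numbers pair the libraries. Deviations from the group means correlated by 0.218, -0.235, -0.197, 0.00793 and 0.0962 between libraries of the same number. Of 5 libraries 1 had its own number as the best partner. These values gave little sign of pairing, but 5 pairs cannot settle it. With the run of library numbers as a covariate 2653 genes passed (729 higher, 1924 lower), and limma called 0 genes for a run by group interaction, with 436 at an unadjusted p under 0.05.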

Other observations

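The tests of EGF receptor signalling and of citrulline and proline synthesis were chosen before their genes were looked at, though the ideas came from genes already seen. Groups of genes described first were fixed before the data were examined and were not called by camera.

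Bile acid and clock genes changed in part. Of 10 bile acid genes 4 fell, 5 when adjusted over the list alone: besides Fgf15, these were Osgin1 (312 ± 39.8 to 198 ± 31.7 FPKM), Slc51a, which exports bile acids (-0.80, adjusted p = 0.0191), and Nr0b2, a repressor induced by the bile acid receptor FXR (-0.88, adjusted p = 0.0205). Slc51a did not pass with the mitochondrial genes left out of the scaling (adjusted p = 0.0635), nor Nr0b2 without NCD replicate 1 (adjusted p = 0.0575). Neither passed after quantile normalization (Slc51a 0.112, Nr0b2 0.0801) or median centring (0.0634 and 0.0617). Nr0b2 also missed the threshold with the replicate block (0.0508), and with HCD replicate 1 and the mitochondrial genes both left out (0.0950). The bile acid list had a median of -0.50 (camera adjusted p = 0.216), or -0.34 with the mitochondrial genes left out of the scaling, and the fry test, run as deposited, called it down (adjusted p = 0.00938). Of 14 clock genes 3 rose and 4 fell, 4 and 4 when adjusted over the list alone. Nr1d1, a repressor of the clock, fell from 472 ± 79.7 to 210 ± 59.4 FPKM, and Nfil3 fell from 50.2 ± 13.4 to 22.6 ± 2.89. Dbp rose from 50.6 ± 26.9 to 127 ± 24.9 FPKM and Tef from 17.7 ± 3.16 to 31.1 ± 3.24. Chosen after their values were seen, Hlf rose by 0.84 on the log2 scale and Arntl (-1.29) and Npas2 (-0.75) fell. The clock list's median was 0.21 (camera adjusted p = 0.118), and the hour at which the mice were killed is not given in the sources used here. With the mitochondrial genes left out of the scaling the clock median was 0.37, with 4 genes higher and 3 lower. After median centring it was 0.36, with 5 higher and 4 lower. Of 17 immediate-early and heat shock genes 7 fell, among them Ier2 (1011 ± 97.6 to 493 ± 46.6 FPKM), Fosb (-0.77), Egr1 (-0.83) and Hspa8 (-0.88), with a list median of -0.31 (camera adjusted p = 0.143), or -0.14 with the mitochondrial genes left out of the scaling and -0.07 after quantile normalization. The fry test, run as deposited, called this list down too (adjusted p = 0.0162). Hspa8 did not pass after quantile normalization (adjusted p = 0.0543).

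Retinoid, fat and antimicrobial genes moved in both directions. Bco1, which splits carotene into retinal, rose from 0.528 ± 0.371 to 7.32 ± 5.07 FPKM, while Isx, its repressor in the gut, fell from 71.1 ± 4.94 to 45.4 ± 13.3 and Dhrs3 fell from 105 ± 8.49 to 54.6 ± 6.66. Isx did not pass after quantile normalization (adjusted p = 0.0957). Rdh7 differed by -0.42 (adjusted p = 0.0544), and passed without HCD replicate 2 (-0.49). Of 11 retinoid genes 1 rose and 2 fell, 1 and 3 when adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.720). Of 23 genes of fat uptake and lipoprotein assembly 6 rose and 3 fell. Apoc3 rose from 842 ± 364 to 1693 ± 423 FPKM, while Plin2, which coats lipid droplets, fell from 237 ± 31.1 to 125 ± 24.04, as did, chosen after their values were seen, Agpat2 (-0.41) and Abcg8 (-0.43). Their list had a median of -0.01 and a mean of 0.14. With the mitochondrial genes left out of the scaling 7 of the 23 were higher and 1 lower, the median was 0.16 and camera called the list up (adjusted p = 0.0175, and 0.474 with an estimated correlation). Of 14 antimicrobial genes 3 rose and 3 fell: Nlrp6 fell from 193 ± 21.6 to 97.3 ± 16.2 FPKM, Cxcl16 from 37.9 ± 4.41 to 20.6 ± 3.12 and Reg3a from 606 ± 109 to 279 ± 76.4, while, besides Saa1, Sprr2a3 (2.24) and Sprr1a (1.12), chosen after their values were seen, rose. This list had a median of 0.07 (camera adjusted p = 0.395). The median was 0.25 with the mitochondrial genes left out of the scaling, and its sign turned after rescaling to TPM (-0.07, 15 genes tested).

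Other lists that were not called had few members past the test, all chosen after their values were seen. Cholesterol synthesis (25 genes, median -0.20, adjusted p = 0.687) had 5 genes lower, among them Stard4 (-0.74), Hsd17b7 (-0.73), Pmvk (-0.54) and Acat2 (-0.52), 4 genes when adjusted over the list alone and 1 with the mitochondrial genes left out of the scaling. Stem cell markers (10 genes, median -0.45, adjusted p = 0.554) had Olfm4 (-1.18), Sox9 (-0.95) and Slc12a2 (-0.61) lower, 5 when adjusted over the list alone and 1, Sox9, with the mitochondrial genes left out of the scaling. Short-chain fatty acid genes (9 genes, median 0.01, mean -0.07, adjusted p = 0.652) had Slc16a1 (-0.85) and Gpr35 (-0.84) lower and Slc16a3 (0.67) higher, or 1 higher and 0 lower with the mitochondrial genes left out of the scaling. Sugar genes (15 genes, median -0.14, adjusted p = 0.556) had Mlxipl (-0.69) lower and Treh (0.57) higher, the lower one alone when adjusted over the list alone, and camera placed the list above other genes. The sign of the sugar median turned, to 0.03 with the mitochondrial genes left out of the scaling and 0.12 after quantile normalization. Peptide genes (18 genes, median 0.01, adjusted p = 0.216) had Slc6a20a (-0.68) lower and Ace (0.72) higher. Xenobiotic genes (28 genes, median -0.33, adjusted p = 0.872) had Gstm3 (-0.99) and Gstm1 (-0.53) lower, 1 gene when adjusted over the list alone. Gut segment markers showed Gata4 (-1.002) lower and Bco1 higher among 5 proximal genes (median 0.29, adjusted p = 0.446), Fgf15 and Osr2 (-0.97) lower among 7 distal genes (median 0.30 but mean -0.22, adjusted p = 0.764) and Car4 (-0.79) lower among 5 colon genes (median 0.41, adjusted p = 0.652). Goblet cell genes had a median of -0.19 (12 genes, adjusted p = 0.687), and camera placed them above other genes. With the mitochondrial genes left out of the scaling, 1 sugar gene was higher and 0 lower, 3 peptide genes higher and 0 lower, 1 xenobiotic gene higher and 1 lower, and 0 colon genes lower. In that scaling the median was -0.04 for cholesterol synthesis, -0.16 for xenobiotic genes, -0.19 for retinoid genes, -0.35 for stem cell markers and -0.04 for goblet cell genes. It was 0.18 for peptide genes and 0.12 for short-chain fatty acid genes. For proximal, distal and colon genes it was 0.42, 0.48 and 0.53. In the lists for which no such number is given, the counts adjusted over the list alone were those over all genes.

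Areg, Fosl1, Phlda1 and F3 are induced by growth factors, and lower EGF receptor and ERK signalling in HCD may account for their falls. Of 13 further response genes 7 fell, among them Dusp5 (-1.19), Hbegf (-1.06) and Spry1 (-0.96), while Il1rn (1.20), chosen after its values were seen, rose, all with the mitochondrial genes left out of the scaling. Their median was -0.71, camera gave p = 0.00165 at the preset correlation and p = 0.142 with an estimated correlation, and the exact permutation of library means gave p = 0.00794 with all 5 HCD libraries below the NCD range. Ier3 also stands in the immediate-early list, and a difference in how long the cells were kept before lysis was not tested.

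Lower citrulline and proline synthesis was a further idea, from enzymes of proline and ornithine among the larger changes. Of 9 further genes 1 fell, Cps1 (-0.92), and none rose in limma. The median was -0.15 and camera gave p = 0.427, with p = 0.568 with an estimated correlation and an exact permutation p of 0.0556 over library means, so the idea was neither borne out nor excluded.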
